A study of Mus musculus with 8 samples.

How the data were processed

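The samples were 8 hybridisations of lung RNA from 4 male Fra-2 transgenic mice of 14 weeks, identified by the mouse numbers in the labels, each against a pool of RNA from 4 wild-type males. Per the labels' protocols, total RNA was isolated with RNeasy columns, reverse transcribed and labelled indirectly with Cy3 or Cy5. Each mouse had 1 array with its RNA in Cy5 and 1 with it in Cy3.

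The deposited values are log2 ratios, 1 per probe and array, made by the authors; the background correction, the normalization and the image software are not given in the sources used here. The log2 scale follows from 498 placeholder values. On each array they sat at 1 constant, between 15.9 and 16.3 where the transgenic RNA was in Cy5 and between -15.9 and -15.5 where it was in Cy3. That constant differs from a value shared by 90 to 705 probes of the same array by what a channel at 0 replaced by 1e-05 gives on the log2 scale. Array medians lay between -0.09 and 0.01, so no further centring was applied. Centring and the use of an offset or filter by the authors stay unknown. No spot intensities were used here, so neither a filter on dim probes nor a variance trend on intensity could be applied, and signal over background is unknown.

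The design fixed before the data were examined took values as deposited. As a departure from it, the 498 placeholders (any value beyond 10 in size) were set to missing, since a single one would set the mean of a mouse. A further 706 values were missing as deposited. A probe entered the tests if each of the 4 mice had at least 1 value, which left 20621 probes and excluded 173.

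Dye-swapped arrays of the same mouse correlated at 0.389 to 0.685, so the ratios run one way on all 8 arrays and none was turned. The direction, transgenic over pool, is likely only and rests on the channel order in the labels. The planned check on the transgene could not be made, because the annotation used here names no probe of Fosl2.

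Gene names come from a platform annotation that pairs probe numbers with genes. At equal numbers, probes of the same gene did not agree: the Spearman correlation over pairs of probes was 0.027. All 6001 offsets up to 3000 numbers each way were tried, and at an offset of 11 the correlation was 0.212 over 4467 pairs, against at most 0.059 at any other. The same offset was best on a random part of the genes, and on the remaining genes it gave 0.204 over 2239 pairs. It was the best of 121 nearby offsets in 18 of 20 blocks of 1000 numbers. The exceptions start at numbers 8000 (0.088) and 13000 (0.112). Of genes named by the rule below, the names of Cidec, AA467197, Atp5b, Birc5, Pln and 1 of 2 probes of Sparcl1 lie there. Genes named only after their values were seen were not checked against these blocks. Annotation numbers above 20237 showed no agreement (-0.007 over 209 pairs), so 475 annotated probes there were left unnamed. In all 12296 probes received 1 gene name, 0 had several, and 8498 are unnamed here; they cover 8741 genes. Of 173 genes with 2 probes that both changed, 142 had both in the same direction, while 75 genes had probes called in opposite directions. Symbols were updated through gene identifiers with the RefSeq table of assembly GRCm38.p6. Near-identical gene copies can cross-hybridise, and probe sequences were not used here. No coordinates are printed because no genome build is given in the sources used here.

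The 2 arrays of a mouse were averaged, so n = 4 mice, and the mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 residual and 4.49 prior degrees of freedom, Benjamini-Hochberg, adjusted p under 0.05). The ratio against 0 leaves out the spread of the control, since the pool is 1 sample. Adjusted p-values beside top probes come from the test over probes; those beside genes of a list come from the same test on values averaged over the probes of a gene. The 37 lists, covering 1236 genes of which 699 were measured, were tested with camera at a preset correlation of 0.01 on gene-level mouse means, with at least 5 measured members, Benjamini-Hochberg over lists. Differences between mice were tested with a limma F test on the 8 arrays with the dye as covariate, over the 20392 probes measured on all 8. Dye effects were tested with limma on the within-mouse difference of the 2 arrays. Correlations over probes are descriptive, as probes are not independent replicates. Offsets, tests of single explanations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

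Named genes followed a rule set before the data were examined: Fosl2; among named probes past the threshold with the same sign on all 8 arrays, the 12 highest and 12 lowest means, 1 probe per gene; up to 4 members of each list past the threshold by size; the 6 named probes with the largest range among those that differ between mice; and the 4 largest named dye effects, of which there were 0.

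All tests were tested on simulated data with the real spread over 20392 probes. Of probes changed by 1 on the log2 scale 86.0% were recovered with the right sign, and of probes changed by 0.5, 34.0%; 2.83% of calls were of unchanged probes. With unchanged mice the mean number of calls over 10 draws was 0. When the pool was drawn as the mean of 4 mice with the same spread as the transgenic mice, the most calls in any of 10 draws was 1. In these draws the pool varied for each probe on its own, and no probe was changed. They cannot show how many calls a pool error shared by genes gives, or a pool error where many probes change. The F test recovered 78.5% of probes in which mice differed by 1 in either direction from their mean. Of calls of the dye test, 6.2% were of probes with no dye effect. The list test called 4 of 4 lists shifted by 0.4, with noise independent between genes. So it cannot show how that test behaves where genes of a list vary together, as macrophage genes did (estimated correlation 0.48).

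Alternatives fixed beforehand were centring, scale and quantile normalization, each mouse left out and each dye orientation alone. Arrays kept apart with the mouse as a block, with and without a dye term, were fixed then too. So were missing-value filters, probes averaged per gene, robust eBayes, other thresholds, a turned sign and other list tests. Alternatives chosen after seeing the data were the values as deposited, names at equal numbers and mouse 4 from its Cy5 array alone. Each mouse left out of the F test and sign flips of the mice were also chosen then.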

Results

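Lung RNA from 4 male mice transgenic for Fra-2 was compared with wild-type lung on 2-colour spotted arrays. Fra-2, the product of Fosl2, is a member of the AP-1 family of transcription factors. The mice were 14 weeks old, on a C57BL6 x CBA background. Each transgenic mouse was hybridised on 2 arrays with the dyes exchanged, which makes 8 arrays, and the other channel always held one pool of lung RNA from 4 wild-type males of the same age. The pool is the only control, so it counts as 1 control sample. The arrays carried 20794 probes and gave 20585 to 20729 usable log2 ratios each, with array medians between -0.09 and 0.01. The number of mice, 4, and the 1 pool limit the precision. The study also covered mice of 6 and 10 weeks, which are not analysed here.

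Values are given as transgenic over pool. This direction is likely only: the labels put the transgenic RNA in channel 1 and the pool in channel 2 on all 8 arrays, and no source used here states how the ratio was formed. If the sign were the other way, higher and lower would exchange throughout. Gene names rest on a fixed offset of 11 between the probe numbers of the annotation and those of the values, found from how well probes of the same gene correlated.

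**Figure D1:**
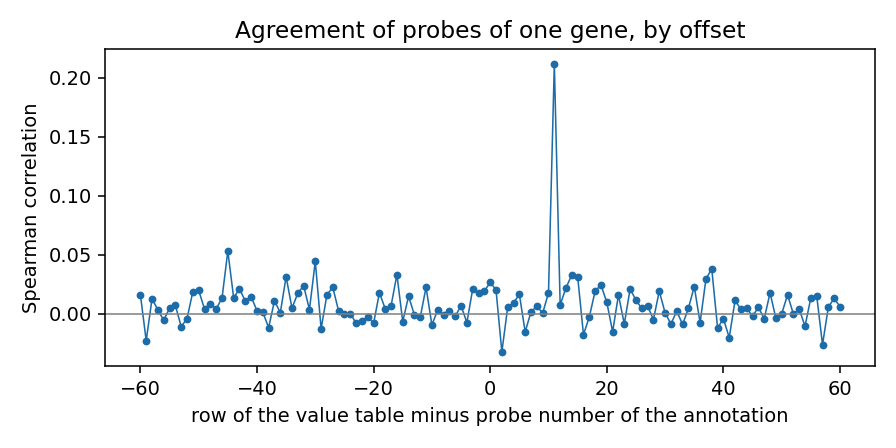
Spearman correlation of log2 ratios between probes of the same gene (y axis) against the offset between value row and annotation number (x axis), 1 point for each of the 121 offsets nearest 0. The point at 11 stands at 0.212, and no other of the 6001 offsets tried is above 0.059.

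The first comparison asked which transcripts differed between 14-week transgenic lung and the wild-type pool. Among named probes with the same sign on all 8 arrays, the largest rises were in Retnla, Ccl8 and Chil3, which all stand in the list of goblet cell and type 2 inflammation genes. Retnla, which encodes the secreted protein RELM-alpha, was 62.2-fold higher (log2 5.96 ± 0.46, SD, n = 4 mice, adjusted p = 2.3e-05). The chemokine gene Ccl8 was 24.1-fold higher (4.59 ± 0.87, adjusted p = 5.8e-04), and the chitinase-like gene Chil3 was 21.6-fold higher (4.43 ± 0.41, adjusted p = 3.9e-05). The largest falls among such probes were in Car3 and in Marco, a scavenger receptor gene of alveolar macrophages. Car3, which encodes carbonic anhydrase 3, fell by 3.29 ± 1.47 on the log2 scale (adjusted p = 0.00415) on the lowest of its 3 probes. Its other probes gave -1.46 and -2.01. Marco fell by 2.54 ± 0.28 (adjusted p = 1.4e-04).

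By limma on the mouse means, 5302 of 20621 probes changed, 2283 higher and 3019 lower. These were 25.7% of the probes tested. Of the 5302, 4095 had the same sign on all 8 arrays, 145 were at least 2-fold higher and 134 at least 2-fold lower. At the gene level, 2772 of 8692 named genes changed, 1175 higher and 1597 lower. The ratio against 0 leaves out the spread of the control, since there was 1 pool. The count fell to 2547 without mouse 1, to 2834 without mouse 2 and to 3190 on the arrays with the transgenic RNA in Cy3 alone.

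The other 9 of the 12 highest named probes follow; all were taken from probes with the same sign on all 8 arrays, so their like sign in 4 of 4 mice comes from that choice. Fbp1, which encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase, was 14.4-fold higher (log2 3.85 ± 1.61), and AA467197 was 12.9-fold higher (3.69 ± 0.34). The chemokine gene Ccl9 (3.11 ± 0.81), the acute phase gene Saa3 (2.94 ± 0.62) and Slc26a4, which encodes the anion exchanger pendrin (2.86 ± 0.94), followed. Ctsk, the gene of cathepsin K, rose by 2.72 ± 0.67 and Bglap, the gene of osteocalcin, by 2.42 ± 0.55. Gpnmb rose by 2.39 ± 1.48. Lcn2, which encodes lipocalin 2, rose by 2.38 ± 0.54 on that probe, while its other probe gave -0.52. Adjusted p for these 9 lay between 3.9e-05 and 0.0117.

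The other 10 of the 12 lowest named probes were taken in the same way. The adiponectin gene Adipoq fell by 2.04 ± 0.40 on the log2 scale and Thrsp, a gene of lipid synthesis, by 1.97 ± 0.29. Pon1, the gene of paraoxonase 1, fell by 1.93 ± 0.86, Pcolce2 by 1.93 ± 0.54 and Igfbp3 by 1.90 ± 0.45. The myoglobin gene Mb fell by 1.81 ± 0.60. Inmt fell by 1.57 ± 0.43, the phosphatase gene Dusp1 by 1.57 ± 0.27 and Bex2 by 1.56 ± 0.17. Ednrb, the endothelin receptor B gene, fell by 1.56 ± 0.44 on 1 probe and had a mean of -0.19 on its other probe. Adjusted p for these 10 lay between 5.3e-04 and 0.00427.

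**Figure D2:**
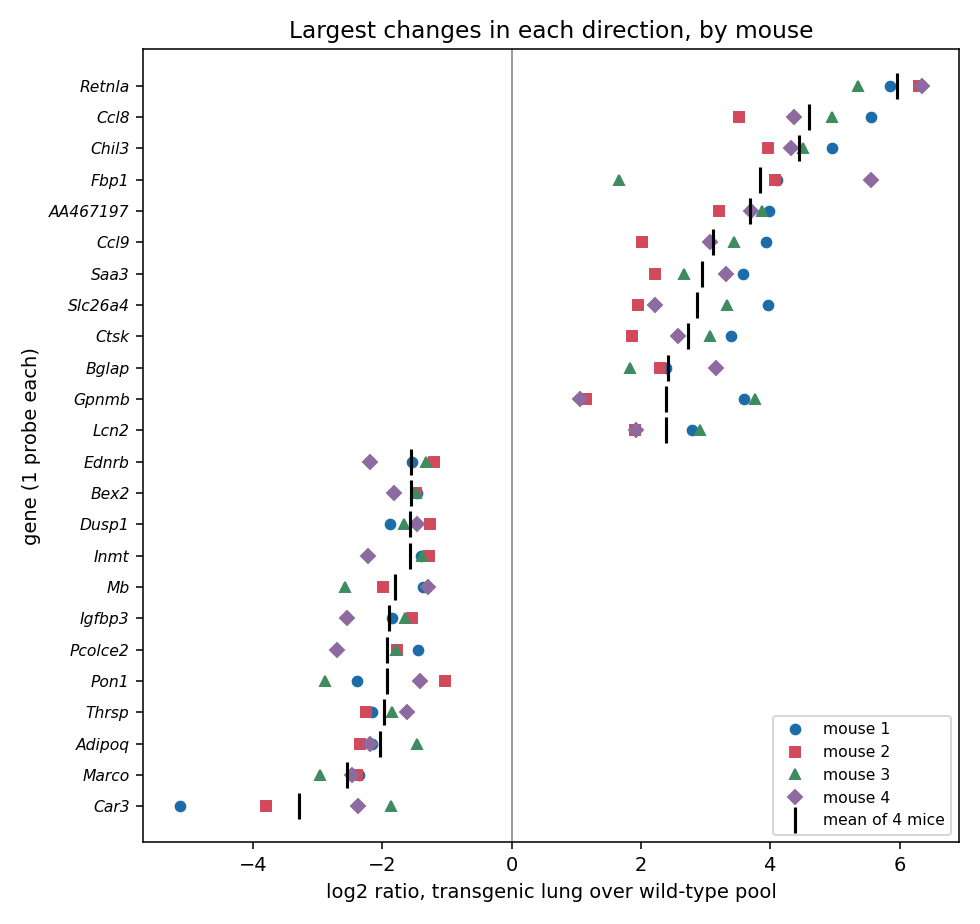
Log2 ratio of transgenic lung over wild-type pool (x axis) for the 12 highest and 12 lowest named probes (y axis), with 1 symbol per mouse (mean of its 2 arrays) and a bar at the mean of 4 mice. Probes were chosen to have the same sign on all arrays, and Fbp1 spans 1.66 to 5.55.

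The second comparison asked which of 37 gene lists, fixed before the data were examined, were shifted against all other genes. By camera with a preset correlation of 0.01, 17 lists passed, 10 higher and 7 lower. With a correlation estimated from the 4 mice, 0 lists passed and 1 had an unadjusted p under 0.05. So each adjusted p with an estimated correlation stands beside its list. By fry, which does not compare a list with other genes, 12 passed, among them Wnt signalling (adjusted p = 0.0462). Of the 17, macrophage (adjusted p = 0.0557), cytokine, chemokine and receptor (0.0598) and fibroblast genes (0.0764) did not pass by fry. Neither did matrix protease (adjusted p = 0.0851), MHC class II (0.113) or T cell and NK cell genes (0.162). Counts are of genes past the threshold over all genes, followed by those adjusted over the list alone. Genes that moved against their list were named after their values were seen, where they fall outside the naming rule. Of these, Tslp, Blk, Il1b, Junb, Orm1, S100a9 and Tgfbi missed the threshold without at least 1 mouse (adjusted p = 0.0507 to 0.178). Of genes named for the 17 lists, Gata3, Il1b, Orm1 and Tpx2 missed it on the Cy5 arrays alone (adjusted p = 0.0575 to 0.124), and Blk, Cd74, Clec9a, Irf4, S100a9, Tgfbi and Tslp on the Cy3 arrays alone (adjusted p = 0.0544 to 0.51).

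Genes of goblet cells and type 2 inflammation had the highest median, 1.37 on the log2 scale over 16 measured genes. Of these, 11 were higher and 3 lower, or 12 and 3 adjusted over the list alone (adjusted p = 9.0e-05, and adjusted p = 0.657 with an estimated correlation). The rises were led by Retnla, Ccl8, Chil3 and Slc26a4, and 9 of the 16 genes also stand in other lists. The 3 that fell were Postn, the periostin gene (-1.08), the transcription factor gene Gata3 (-0.43) and Tslp (-0.39). Gata3 was no longer past the threshold without mouse 1, 2 or 4 (adjusted p = 0.113 to 0.145).

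Macrophage genes were higher in 19 and lower in 3 of 29 measured genes, or 20 and 4 adjusted over the list alone, with a median of 0.64. The list passed at adjusted p = 5.5e-06, and at adjusted p = 0.663 with an estimated correlation. Beside Chil3, Ccl9 and Ctsk, the complement gene C1qa rose by 1.89 ± 0.75. Marco, the fatty acid binding protein genes Fabp4 (-1.16) and Fabp1 (-0.89) fell. The list shared 11 genes with other lists, and 6 of its genes also differed between mice.

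Cytokine, chemokine and receptor genes were higher in 12 and lower in 4 of 28, or 14 and 5 adjusted over the list alone, with a median of 0.26 (adjusted p = 0.00756, and adjusted p = 0.663 with an estimated correlation). Ccl6 rose by 2.25 ± 0.48 and Ccl12 by 2.13 ± 0.72, beside Ccl8 and Ccl9. Cxcl14 (-0.82), Vegfa (-0.71), Il1b (-0.50) and Ccl27a (-0.49) fell. Genes of matrix proteases and their inhibitors were higher in 16 and lower in 2 of 27, or 16 and 4 adjusted over the list alone, with a median of 0.45 (adjusted p = 0.00141, and adjusted p = 0.693 with an estimated correlation). Ctsk, Adam8 (1.29 ± 0.24) and the cathepsin S gene Ctss (1.22 ± 0.51) rose, and Timp3 (-1.07) and Mmp9 (-0.37, the mean of probes at -0.74 and 0.001) fell.

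MHC class II and antigen presentation genes were higher in 9 and lower in 1 of 15, or 10 and 1 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.00297, and adjusted p = 0.693 with an estimated correlation). The lysosomal thiol reductase gene Ifi30 (1.27 ± 0.34) and H2-Eb1 (0.85 ± 0.45) rose, as did the invariant chain gene Cd74 (0.75 ± 0.58), and Clec9a (-0.56) fell. Cd74 missed the threshold without mouse 1 (adjusted p = 0.0887) or mouse 3 (adjusted p = 0.0819). B cell and plasma cell genes were higher in 8 and lower in 1 of 13, or 8 and 2 adjusted over the list alone, with a median of 0.52 (adjusted p = 0.00481, and adjusted p = 0.663 with an estimated correlation). Blnk (1.03 ± 0.21), Cd22 (0.996 ± 0.24), Irf4 (0.73 ± 0.45) and Ltb (0.73 ± 0.21) rose, and Blk (-0.29) fell. Irf4 missed the threshold without mouse 4 (adjusted p = 0.0622), and Blk with the mouse as a block (adjusted p = 0.0696, and 0.146 with a dye term). T cell and NK cell genes were higher in 6 and lower in 2 of 16, or 7 and 3 adjusted over the list alone, with a median of 0.28 (adjusted p = 0.0441, and adjusted p = 0.693 with an estimated correlation). Cd2 (0.70 ± 0.22) and the T cell receptor complex gene Cd3g (0.53 ± 0.20) rose, while Gata3 and the granzyme A gene Gzma (-1.09 ± 0.92) fell. Cd3g lost its call on the Cy3 arrays alone (adjusted p = 0.429) and Gzma without mouse 2, 3 or 4 (adjusted p = 0.0817 to 0.122). The T cell and NK cell list did not pass without mouse 1 (adjusted p = 0.251), without mouse 3 (adjusted p = 0.089) or on arrays of either dye orientation alone.

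Neutrophil genes were higher in 10 and lower in 4 of 18, both over all genes and adjusted over the list alone, with a median of 0.31 (adjusted p = 0.0133, and adjusted p = 0.663 with an estimated correlation). Beside Chil3, Wfdc21 (1.23 ± 0.70) and the peptidoglycan recognition gene Pglyrp1 (1.11 ± 0.32) rose. The calgranulin genes S100a8 (-1.09 ± 0.66) and S100a9 (-0.42, the mean of probes at -1.04 and 0.19), Il1b and Mmp9 fell, and S100a8 missed the threshold without mouse 4 (adjusted p = 0.0551). Complement and acute phase genes were higher in 8 and lower in 1 of 24, both over all genes and adjusted over the list alone, with a median of 0.11 (adjusted p = 0.0103, and adjusted p = 0.663 with an estimated correlation). Saa3, C1qa, C1qc (1.15 ± 0.55) and Saa1 (1.06 ± 0.23) led them, and Orm1 (-0.37) fell.

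Cell cycle genes were higher in 22 and lower in 0 of 35, or 25 and 0 adjusted over the list alone, with a median of 0.30. The list passed at adjusted p = 3.6e-08, and at adjusted p = 0.663 with an estimated correlation. Birc5, which encodes survivin, rose by 1.12 ± 0.26, the cyclin gene Ccna2 by 0.87 ± 0.16 and the kinetochore motor gene Cenpe by 0.85 ± 0.20. The spindle gene Tpx2 rose by 0.92 ± 0.24. The median was above 0 in 4 of 4 mice, from 0.25 to 0.41.

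Among the 7 lower lists, genes of heart and skeletal muscle had the smallest p. Of 30 measured genes, 22 were lower and 0 higher, or 23 and 0 adjusted over the list alone, with a median of -0.47 (adjusted p = 1.5e-08, and adjusted p = 0.663 with an estimated correlation). Mb, the mitochondrial creatine kinase gene Ckmt2 (-1.40 ± 0.40), the beta myosin heavy chain gene Myh7 (-1.16 ± 0.44) and the troponin C gene Tnnc1 (-1.03 ± 0.33) fell. Adipose tissue genes were lower in 10 and higher in 0 of 14, both over all genes and adjusted over the list alone, with a median of -0.67 (adjusted p = 0.00105, and adjusted p = 0.663 with an estimated correlation). Adipoq, Thrsp, Car3 over its 3 probes (-2.25 ± 0.65) and the lipid droplet gene Cidec (-1.55 ± 0.57) led them. The muscle medians were -0.47, -0.45, -0.66 and -0.33 in mice 1 to 4, and the fat medians -0.56, -0.997, -0.59 and -0.71.

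Type 1 alveolar epithelium genes were lower in 8 and higher in 0 of 12, both over all genes and adjusted over the list alone, with a median of -0.36 (adjusted p = 0.00527, and adjusted p = 0.663 with an estimated correlation). Emp2 (-0.98 ± 0.26), the receptor gene Ager (-0.78 ± 0.23) and Vegfa (-0.71 ± 0.11) fell in 4 of 4 mice. Timp3 fell by 1.07 ± 0.23 as the mean of 4 probes, which ranged from -1.42 to -0.08. Smooth muscle and myofibroblast genes were lower in 10 and higher in 1 of 18, or 12 and 2 adjusted over the list alone, with a median of -0.30 (adjusted p = 0.00842, and adjusted p = 0.663 with an estimated correlation). The phospholamban gene Pln (-1.20 ± 0.10), Synpo2 (-0.79 ± 0.34) and Notch3 (-0.64 ± 0.34) fell, and the coactivator gene Myocd rose (0.72 ± 0.09). Pln is also a gene of heart muscle and Synpo2 of skeletal muscle, whose list had a median of -0.47. Fibroblast genes were lower in 8 and higher in 2 of 16, or 9 and 2 adjusted over the list alone, with a median of -0.40 (adjusted p = 0.0246, and adjusted p = 0.693 with an estimated correlation). Inmt and Npnt (-1.19 ± 0.40) fell, and S100a4 (1.47 ± 0.32) and Cd34 (1.17 ± 0.49) rose.

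Genes of TGF-beta and BMP signalling were lower in 9 and higher in 2 of 23, or 10 and 2 adjusted over the list alone, with a median of -0.25 (adjusted p = 0.04, and adjusted p = 0.663 with an estimated correlation). Bmp6 (-1.38 ± 0.36), Ltbp4 (-1.02 ± 0.26) and Bmp4 (-0.53 ± 0.17) fell, and Bmpr1b (0.67 ± 0.41) and Tgfbi (0.28) rose. The list did not pass without mouse 2 (adjusted p = 0.0774) or on the Cy3 arrays alone (adjusted p = 0.0982). Bmpr1b did not pass without mouse 2 (adjusted p = 0.0576) or mouse 4 (adjusted p = 0.0505). Immediate early and handling stress genes were lower in 10 and higher in 1 of 24, both over all genes and adjusted over the list alone, with a median of -0.26 (adjusted p = 0.0103, and adjusted p = 0.663 with an estimated correlation). Dusp1, the nuclear receptor gene Nr4a1 (-1.13 ± 0.23) and the AP-1 genes Fosb (-0.77 ± 0.47) and Jun (-0.66 ± 0.22) fell, and Junb (0.37) rose. With 1 pool, a difference in how the pool tissue was handled cannot be told apart from a change in the transgenic lungs.

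**Figure D3:**
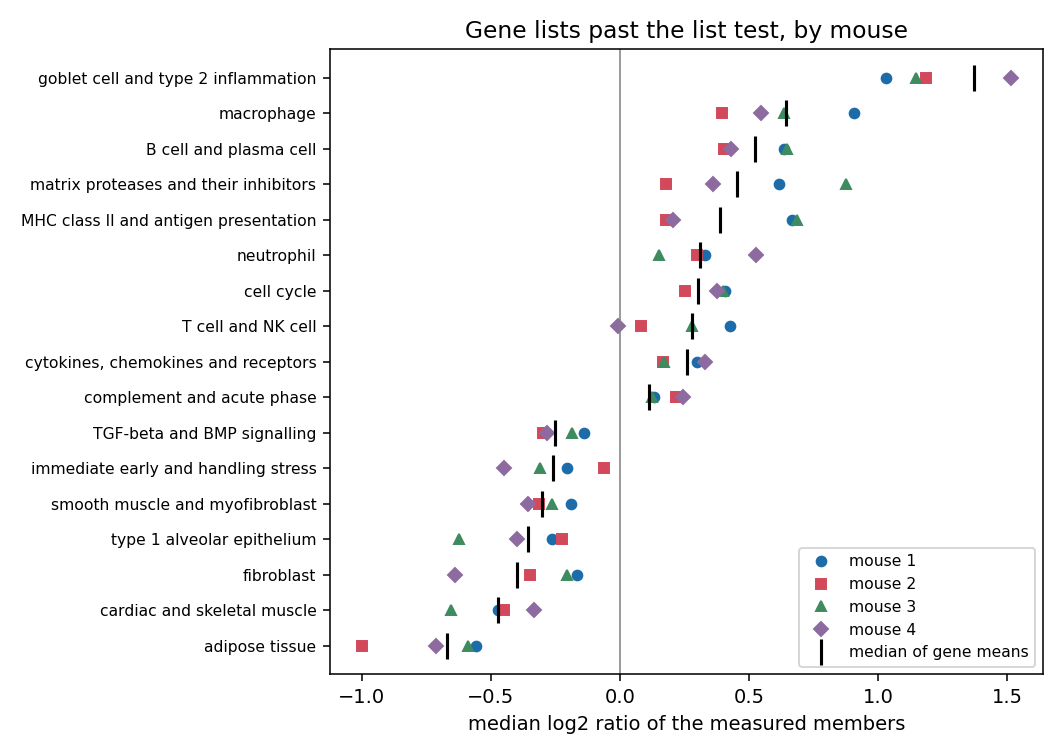
Median log2 ratio over the measured members (x axis) of the 17 gene lists past camera at the preset correlation (y axis), with 1 symbol per mouse and a bar at the median of the 4-mouse gene means. The bars run from -0.67 for adipose tissue to 1.37 for goblet cell and type 2 inflammation genes.

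The other 20 lists did not pass. Where no second count is given, the count adjusted over the list alone was equal. These genes of the 20 lists fall outside the naming rule and were chosen after their values were seen, so that counts of 5 or fewer could be named in full: Krt15, Sftpb, Scd1, Sox17, Ramp2, Plvap, Pdgfa, Junb, Jdp2, Fzd8, Dhcr7, Acsl4, Oas1a and B2m.

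Fibrillar collagen and fibrotic matrix genes had 1 higher and 7 lower of 35 (median -0.16, adjusted p = 0.0838). Ogn (-1.41 ± 0.43), Postn and the decorin gene Dcn (-0.88 ± 0.25) fell, and the elastin gene Eln rose (0.67 ± 0.55), a call that was lost without mouse 1, 3 or 4 (adjusted p = 0.088 to 0.106). The list passed as lower without mouse 1 (adjusted p = 0.0265) or mouse 3 (adjusted p = 0.00372). Basement membrane genes had 0 higher and 4 lower of 10 (median -0.32, adjusted p = 0.104), which were Npnt, Sparcl1 (-0.86), Lama4 (-0.59) and Lamb2 (-0.37); the list passed without mouse 3 (adjusted p = 0.0222). Mesothelium genes had 3 higher and 1 lower of 6 (median 0.36, adjusted p = 0.0648) and passed without mouse 1 (adjusted p = 0.0408) or mouse 3 (adjusted p = 0.0107). The mesothelin gene Msln (1.31 ± 0.17), Krt18 (0.70) and Cpe (0.38) rose, and Igfbp6 (-0.46) fell.

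Club cell genes had 1 higher and 6 lower of 17 (median -0.56, adjusted p = 0.0826). Pon1, Cyp4b1 (-1.38 ± 0.32), Gsta3 (-1.23 ± 0.60) and Ces1f (-0.91 ± 0.43) fell, and Krt15 rose (0.80 ± 0.74). The club cell medians were -0.87, 0.07, -0.97 and -0.11 in mice 1 to 4, and 10 of the 17 genes differed between mice. The list passed without mouse 2 (adjusted p = 0.00648), without mouse 4 (adjusted p = 0.029) and on the Cy3 arrays alone (adjusted p = 0.0223). Ciliated cell genes had 1 higher and 3 lower of 19, or 0 and 1 adjusted over the list alone (adjusted p = 0.999). Rfx3 (0.30) rose, and Mlf1 (-0.89 ± 0.77), Tuba1a (-0.50) and Ift88 (-0.43) fell. Type 2 alveolar epithelium genes had 5 higher and 1 lower of 18 (adjusted p = 0.466), with a median of -0.02 below 0 while the mean, 0.19, and the test lay above. Slc26a4, Chil1 (1.74 ± 0.31), Hc (0.64), the surfactant protein gene Sftpb (0.37) and Scd1 (0.36) rose there, and Bex2 fell.

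Vascular genes moved both ways. Endothelium genes had 2 higher and 5 lower of 19 (adjusted p = 0.593). Sox17 (0.57) and Ramp2 (0.40) rose. Icam2 (-0.99 ± 0.48), Ednrb, the endoglin gene Eng (-0.61 ± 0.29) and Plvap (-0.60) fell, as did Flt1 (-0.60, the mean of probes at -1.10 and -0.10). Vasoactive and pulmonary hypertension genes had 1 higher and 4 lower of 16 (adjusted p = 0.834). The thromboxane synthase gene Tbxas1 rose by 0.61 ± 0.19 as the mean of probes at -0.22 and 1.43, and Ednrb, Acvrl1 (-0.56), the prostacyclin synthase gene Ptgis (-0.43) and Pdgfa (-0.36) fell. The AP-1 and related bZIP genes had 2 higher and 4 lower of 9, or 3 and 4 adjusted over the list alone (adjusted p = 0.745). Batf (0.68 ± 0.31) and Junb rose, and Fosb, Mafk (-0.68 ± 0.17), Jun and Jdp2 (-0.53) fell. Wnt signalling genes had 1 higher and 4 lower of 20 (adjusted p = 0.466): Sfrp2 (0.51) rose, and Dkk3 (-0.59), Wif1 (-0.53 ± 0.12), Sfrp4 (-0.44) and Fzd8 (-0.35) fell.

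Oxidative and xenobiotic defence genes had 8 higher and 13 lower of 33, or 8 and 15 adjusted over the list alone (median -0.25, adjusted p = 0.0826). Gstm1 (-1.14 ± 0.52) and the catalase gene Cat (-1.02 ± 0.18) fell. The list passed as lower without mouse 2 (adjusted p = 0.0216) and on the Cy3 arrays alone (adjusted p = 0.0314). Lipid and surfactant metabolism genes had 3 higher and 8 lower of 30 (adjusted p = 0.412): Dhcr7 (0.54), Acsl4 (0.46) and Scd1 rose, and the ATP citrate lyase gene Acly (-1.11 ± 0.34), Scd2 (-0.77 ± 0.17) and the lipoprotein lipase gene Lpl (-0.71 ± 0.34) fell. Oxidative phosphorylation genes had 8 higher and 11 lower of 53 (adjusted p = 0.514), with the largest changes in Atp5j (-0.64 ± 0.17), Atp5b (-0.58 ± 0.26), Ndufc1 (-0.57 ± 0.22) and Ndufv1 (-0.56 ± 0.21). Ribosomal protein genes had 9 higher and 6 lower of 55, or 6 and 5 adjusted over the list alone (adjusted p = 0.471); they passed as higher without mouse 4 (adjusted p = 0.0293) and on the Cy5 arrays alone (adjusted p = 0.00125). Rpsa (0.81 ± 0.17), Rps26 (0.66 ± 0.14), Rps9 (0.51 ± 0.36) and Rplp2 (0.46 ± 0.16) rose.

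Interferon response genes had 2 higher and 3 lower of 17 (adjusted p = 0.514): Irf1 (0.66 ± 0.34) and Oas1a (0.40) rose, and Ifit3 (-0.68 ± 0.29), Igtp (-0.61) and Ifi27l2a (-0.54) fell. MHC class I and antigen processing genes had 3 higher and 2 lower of 13, or 5 and 3 adjusted over the list alone (adjusted p = 0.333). Psmb10 (0.51), Psme2 (0.48) and B2m (0.31) rose, and Tap1 (-0.59) and H2-T23 (-0.39, the mean of probes at -0.66 and -0.12) fell. Eosinophil, mast cell and basophil genes had 2 higher and 2 lower of 11 (adjusted p = 0.745): Mcpt8 (0.51) and Cyp11a1 (0.36) rose, and Prg3 (-0.49) and Gata2 (-0.30) fell. Red blood cell genes had 2 higher and 1 lower of 9 (adjusted p = 0.491): Klf1 (0.47) and Kel (0.42) rose, and Hba-a1 (-0.61 ± 0.16) fell over 6 probes. Platelet genes had 1 higher of 6, Gp9 (0.43, adjusted p of the list = 0.579), and thymus and lymph node genes 1 higher of 9, Dntt (0.25, adjusted p of the list = 0.466), both 0 adjusted over the list alone. Among the genes that the naming rule took from these 20 lists, Sparcl1, Lama4, Lamb2, Krt18, Rfx3, Mlf1, Ift88, Acvrl1, Ptgis, Sfrp2, Igtp, Psmb10, Psme2, H2-T23, Mcpt8, Cyp11a1, Gata2, Gp9, Rps9 and Dntt each missed the threshold without at least 1 mouse (adjusted p = 0.0503 to 0.173). Of those chosen after their values were seen, B2m, Dhcr7, Fzd8, Jdp2, Junb, Krt15, Oas1a, Pdgfa, Plvap, Ramp2, Scd1 and Sftpb did as well (adjusted p = 0.051 to 0.141). Of genes named for the 20 lists, Acvrl1, Gata2, Gp9, H2-T23, Jdp2, Krt15, Lamb2, Mlf1, Plvap, Ptgis, Rfx3, Sfrp2 and Tap1 missed it on the Cy5 arrays alone (adjusted p = 0.0506 to 0.279), and B2m, Dntt, Eln, Fzd8, Gata2, Ift88, Klf1, Krt18, Oas1a, Pdgfa, Psmb10, Psme2, Ramp2, Rplp2, Rps9 and Sftpb on the Cy3 arrays alone (adjusted p = 0.0609 to 0.698). Dntt also missed it with the mouse as a block (adjusted p = 0.134, and 0.201 with a dye term).

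The third comparison asked whether single transgenic mice differed by more than the spread between their 2 arrays. The gluconeogenic gene Fbp1 had the widest range among named probes, with log2 ratios of 4.09, 4.07, 1.66 and 5.55 in mice 1 to 4 (adjusted p = 0.0178). The collagenase gene Mmp13 was at 2.78, -0.26, 3.54 and 1.497 (adjusted p = 0.0178), and its call against the pool was lost without mouse 1, 3 or 4. Arg1, which encodes arginase 1, was at 3.58, 0.45, 3.28 and 0.71 on that probe (adjusted p = 0.0114), and its other probe had a mean of 0.64. Gpnmb was at 3.59, 1.15, 3.76 and 1.06 (adjusted p = 0.0114). One probe of Car3 was at -5.12, -3.80, -1.86 and -2.37 (adjusted p = 0.0114), and 1 probe of Gsg1 at 0.42, 1.48, 3.61 and 1.77 (adjusted p = 0.0117). The other probe of Gsg1 had a mean of 0.14 and did not pass against the pool. By a limma F test with a dye term, 201 of 20392 probes differed between the 4 mice, and 53 of them were also among the changed probes. That is near the share over all probes in that test, of which 5278 were changed. At an unadjusted p under 0.05, 3263 probes differed between mice. The count at adjusted p was 495 without mouse 4 and 0, 1 and 0 without mouse 1, 2 or 3. It was 84 with no dye term.

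**Figure D4:**
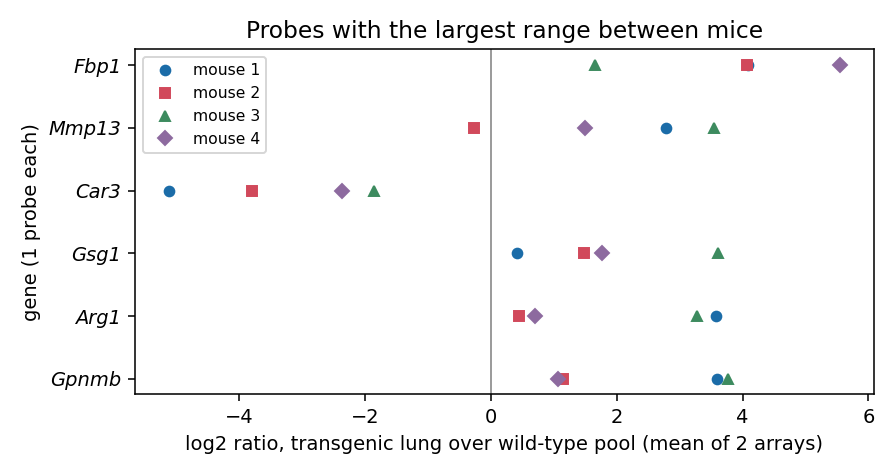
Log2 ratio of transgenic lung over wild-type pool (x axis, mean of 2 arrays) in each of the 4 mice for the 6 named probes with the largest range (y axis). Arg1 and Gpnmb lie above 3 in mice 1 and 3 and at or below 1.15 in mice 2 and 4.

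The last comparison asked how much a ratio depended on the dye that carried the transgenic RNA. By limma on the difference within each mouse, 1 of 20392 probes had a dye effect, and it has no gene name here. At an unadjusted p under 0.05 the count was 4912, a larger share than the 0.05 that chance gives. So the 1 call after adjustment does not show that the other ratios were free of a dye effect. Over all probes, the 2 arrays of a mouse, which carry opposite dyes, correlated at a median of 0.615 (0.389 to 0.685). Arrays of different mice correlated at a median of 0.577 with the same dye (0.473 to 0.715) and 0.462 with opposite dyes (0.204 to 0.599). Without mouse 1 the count of dye effects was 0.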

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

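All tests of explanations here were chosen after the results were seen. A value counts as apart when its gap to the nearest other, over the whole range, passes Dixon's 95% limit, which chance passes in about 1 of 20 groups; of 230 such groups looked at, 15 passed, with Marco, Inmt and Bex2 counted both as probes and as list genes.

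The array of mouse 4 with the transgenic RNA in Cy3 stood apart from the other 7. Its log2 ratios had an interquartile range of 0.906, against 0.451 to 0.521 on the others, an SD of 0.768 against 0.413 to 0.457, and a median of -0.093 against -0.02 to 0.008. Among genes, mouse 4 lay below the others for Inmt (-2.21 against -1.40 to -1.28), Bex2 (-1.82 against -1.48 to -1.46) and Tuba1a (-0.72 against -0.44 to -0.42). Mouse 3 lay apart for Marco (-2.96 against -2.46 to -2.36), Myocd (0.59 against 0.75 to 0.78) and Bmp4 (-0.28 against -0.64 to -0.60), and mouse 1 for the calgranulin gene S100a8 (-0.11 against -1.55 to -1.32). Of genes named after their values were seen, mouse 1 lay above the others for Oas1a (0.78 against 0.25 to 0.32) and mouse 4 for Fosl1 (1.004 against 0.14 to 0.28). With mouse 4 taken from its Cy5 array alone, an alternative chosen after seeing the data, 5731 probes changed.

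The median of the heart and skeletal muscle list and that of the fat list were below 0 in 4 of 4 mice. Of their genes, 22 of 30 and 10 of 14 passed as lower. Neither list passed camera with an estimated correlation (adjusted p = 0.663 for both). The 125 genes of all 8 lists of other resident lung cells together had a median above that of the 44 muscle and fat genes in each mouse. The difference was 0.36 ± 0.10 on the log2 scale (SD, n = 4). List medians lay above muscle and fat by 0.59 ± 0.17 for type 2 alveolar epithelium but by 0.12 ± 0.14 for type 1. For fibroblasts the difference was 0.16 ± 0.30 and for club cells 0.03 ± 0.46. These differences cannot decide on dilution of the lung's own cells by infiltrating cells. Dim probes can lie near 0 whatever the cause, and no intensities were used to remove them. Dilution as the whole or a part of the fall stays open. Heart, muscle or fat tissue carried into the wild-type pool at dissection may equally have produced it. The highest of the muscle and fat medians was -0.331, below 0 in each mouse as a shared pool requires. With 1 pool this cannot be told apart from a fall in the transgenic lungs, for Pln and Synpo2 of the smooth muscle list as well. The same limit covers genes of the lipid and macrophage lists that fat can also express, such as Fabp4, Acly, Scd2 and Lpl. A change in the transgenic lung itself, where pulmonary veins hold cardiac muscle of their own, stays open and untested.

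Probes that differ between mice set mice 1 and 3 apart from mice 2 and 4. That split held 72.6% of the between-mouse variance of the 201 probes, and it was the largest of 3 splits in 174 of them. A fault of single arrays is argued against by the deviations from the 4-mouse mean over all probes: taken on arrays of opposite dye orientation, mouse 1 with 3 and mouse 2 with 4 correlated at 0.104 to 0.222, and other pairs of mice at -0.31 to -0.108. A batch that moves probes regardless of the cells they come from is argued against by the spread over all 37 lists, where club cell genes held the most, with 10 of 17 (one-sided Fisher's exact p times 37 = 7.1e-14, with genes that are not independent); a batch that acts by signal strength stays open, as no intensities were used. Less airway in the sampled tissue of mice 1 and 3 cannot be told apart from other differences: club and ciliated cell medians ordered all 6 pairs of mice alike, but mesothelium did too, and 25 of 37 list medians parted mice 1 and 3 from 2 and 4, such as MHC class II (0.66, 0.18, 0.69 and 0.21 in mice 1 to 4), matrix proteases (0.62, 0.18, 0.88 and 0.36) and fibrillar collagens (0.01, -0.37, 0.19 and -0.43), and a biological difference between the mice was not tested.

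Probes of the same gene agreed only after the annotation numbers were moved by 11. Chance among many offsets is argued against by the genes kept aside, where the offset chosen on the others gave a Spearman correlation of 0.204, against at most 0.084 at any other offset. The offset did not hold above annotation number 20237, where it gave -0.007 over 209 pairs and no names were given. Below 20000, a local break cannot be told apart from chance in the block with the lowest correlation, 0.088, with a standard error of 0.055. No biological explanation applies to this pattern.

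Whether chance signs of the 4 mice could give the 5302 changed probes has too few patterns for a share under 0.05. Of 8 sign patterns, 1, the real one, gave as many calls, and the highest of the others gave 0. All 4 mice share 1 pool, so an error of the pool has the same sign in each mouse. Turning the sign of a mouse removes such calls too. These patterns therefore cannot tell a change in the transgenic lungs from an error of the pool.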

How the results depend on the processing

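Where named genes and lists were recomputed, none of those called turned direction, except with the turned sign, which exchanges higher and lower by construction. Named genes were not recomputed with robust eBayes, the missing-value filters or names at equal numbers, nor was the direction of single lists with the last. On the Cy5 arrays alone, 2 of the 3863 probes also called there had the opposite sign. Further, the depth of signal over background is unknown, and what dim probes limit was not measured. On each array 341 to 949 probes shared 1 identical log2 ratio. These values were kept, and the cause of the ties was not tested. Of 5302 changed probes (2283 higher, 3019 lower), leaving out each mouse in turn gave 2547 to 4064 (1011 to 1890 higher, 1536 to 2193 lower), with fewest calls without mouse 1. Arrays with the transgenic RNA in Cy3 alone gave 3190 (1208 and 1982), and probes averaged per gene 2772 (1175 and 1597), where fewer features are tested. At an unadjusted p under 0.05 the count was 8294 (3918 higher), at adjusted p under 0.10 3444 were higher, at 1.5-fold or more 1605 (644 and 961), and by treat against a 1.2-fold change 1001 (414 and 587). Scale and quantile normalization gave 6219 and 6339, the mouse as a block 6546, with a dye term 6152, and values as deposited, chosen after seeing the data, 4607. Of 17 lists, 0 passed with an estimated correlation and 12 lists passed by fry, 11 of them among the 17; with names at equal numbers, chosen after seeing the data, 0 passed. The T cell and NK cell list was lost with centring (adjusted p = 0.0534) and the TGF-beta and BMP list on Cy3 arrays alone (adjusted p = 0.0982); 15 of 17 lists passed in all other alternatives at the preset correlation. Collagen and fibrotic matrix genes passed as lower without mouse 1 (adjusted p = 0.0265) or 3 (adjusted p = 0.00372), and club cell genes without mouse 2 (adjusted p = 0.00648) or 4 (adjusted p = 0.029). Of 201 probes that differ between mice, 84 did with no dye term, 78 with values as deposited and 0 to 495 with a mouse left out, the last 2 chosen after seeing the data. The 1 dye effect ranged from 0 to 1 over left-out mice. Of 164 named genes, 52 lost the call in at least 1 alternative, 46 of them without at least 1 mouse. Besides left-out mice and single dyes, calls were lost with a mouse block (Blk, Dntt), scale normalization (Gata3, Krt15, Mlf1, Mmp13), quantile normalization (Krt15, Mmp13), mouse 4 from 1 array (Blk, Gata2, Gata3, Mlf1) and values as deposited (Cd74, Eln, Gata3, Gp9, Gzma, Ift88, Krt15, Mlf1, Mmp13, Pdgfa, Plvap, Tgfbi). The cause was not tested for these shifts. Using complete probes alone changed nothing in the last 2 tests, which already required them, and an intensity trend and a Fosl2 value had no data.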

Other observations

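Among club cell genes outside the naming rule, chosen after their values were seen, Cyp2f2 was at -1.71, 0.11, -2.15 and 0.05 in mice 1 to 4, the haptoglobin gene Hp at -1.27, 0.07, -1.69 and -0.12, and the secretoglobin gene Scgb3a1 at -0.761, 1.2, -0.484 and 0.855. Their means against the pool did not pass (adjusted p = 0.104, 0.0819 and 0.653), and Hp passed without mouse 2 (adjusted p = 0.0467). With the mouse as a block Cyp2f2 (adjusted p = 0.0365, and 0.0465 with a dye term) and Hp (adjusted p = 0.0239 and 0.0328) passed. That fit takes 8 arrays with 1 within-mouse correlation for all genes, which over probes was 0.069, and 0.301 with a dye term. Where mice differ this much, it counts arrays of the same mouse too nearly as separate replicates. Of the AP-1 genes measured, Fosl1 was at 0.14, 0.19, 0.28 and 1.004 in mice 1 to 4 (adjusted p = 0.0743), and it passed with scale (adjusted p = 0.0364) and quantile normalization (adjusted p = 0.032).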
